A study of Mus musculus with 6 samples.

How the data were processed

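Gene expression was measured by sequencing of polyA RNA from the intestinal epithelium of mice labelled Apoe-/-, a genotype without functional apolipoprotein E that is widely used to study atherosclerosis. Mice had received the fungus Candida albicans or phosphate-buffered saline (PBS) by gavage, every 3 days over 2 weeks. There were 3 libraries per group, named by the group and replicate number in the labels. The labels do not say whether each library came from 1 mouse, so p-values measure only the spread between these libraries. The part of the intestine and the way the epithelium was removed are not given in the sources used here.

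The deposited table holds raw read counts per Ensembl gene, whole numbers with 1 column per library and no normalization. Trim Galore 0.6.7, HISAT2 2.2.1, featureCounts 2.0.1 and the mouse build mm10 are named in the submitters' processing notes. Their parameters, the strand setting and the annotation release are not given in the sources used here. Reads of overlapping genes, antisense genes and near-identical copies (the Ugt1a, Cyp2c, Cyp3a, Reg3, Acaa1 and Defa families) may therefore be shared between them, and single values for such genes are uncertain. Of the 54532 genes in the table, 54495 have an identifier in GENCODE M21 (GRCm38, the assembly of mm10), and 98.33% of these have the same chromosome, start and end there. Symbols that a spreadsheet had turned into dates, 27 in all, were restored from their Ensembl identifiers.

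Totals lay between 21406930 and 24891735 counts per library. A gene with no count in a library can be excluded above 0.113 to 0.148 CPM (counts scaled to a common library size, here the TMM-scaled total), taking 3 counts as the upper limit, for counting error only. No pair of libraries agreed within sampling noise: chi-square per degree of freedom over genes was 36.5 or more for every pair, so each was counted as 1 sample.

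Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept with filterByExpr (minimum count 10, minimum total 15), which left 16313 of the 29031 with a count in any library. Libraries were scaled by the trimmed mean of M values (TMM). The main test was edgeR's quasi-likelihood test (glmQLFit with robust=TRUE and the default legacy setting, glmQLFTest), two-sided, Candida albicans against PBS with no covariate, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Standard errors of log2 fold changes were taken from the fit's F statistic. CPM values use the TMM-scaled totals, and log2 CPM a prior count of 2.

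For gene lists, camera in limma 3.58.1 was run with its preset correlation between genes of 0.01, two-sided, on the 40 of 43 lists with 5 or more tested members. Camera compares a list with the other genes. It was repeated with the correlation estimated from the data, and with fry, which tests whether a list's genes move one way on balance. Fry's mixed test asks whether members change in either direction, without comparing them with the other genes. Members were also adjusted over the list alone. Shares of counts were compared with exact two-sided permutation tests, which cannot go below p = 0.1 with 3 libraries against 3. A smooth muscle score was the mean log2 CPM of 10 markers.

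The design, the lists, the alternatives and the rule for naming genes were set before the data were examined. That rule took the 10 genes with the largest change in each direction among those with an adjusted p under 0.05, a mean of 5 CPM or more in the higher group and no overlap between the groups. Where fewer than 10 passed, the places went to the genes of lowest p that met the other conditions, reported as not past the threshold. Unnamed gene models and single immunoglobulin or T cell receptor segments were left out. It also took up to 4 members of lowest p from each list that was called, and 14 genes named in any case. The values of 1 gene that the rule takes are not reported here. Any other gene is given with a statement that it was chosen after its values were seen, unless it stands as an example from a list.

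Alternatives were DESeq2 size factors, upper quartile scaling, library totals only, the DESeq2 1.42.0 Wald test, limma-voom with and without sample quality weights, robust=FALSE, no count filter, a mean of 5 CPM or more, removal of the mitochondrially encoded genes, the replicate number as a block, and removal of each library in turn. A smooth muscle covariate, legacy=FALSE and removal of replicate 1 of both groups were added after seeing the data. The gene test was tested on simulated counts for the 16313 genes with 200 changed, besides a list of 20 genes all lowered 2-fold. At the dispersions estimated here the gene test recovered 5% of genes changed 2-fold and 45% of those changed 4-fold, and called 0.012% of unchanged genes. At a dispersion of 0.02 it recovered 74% and 98%. Recovery after Benjamini-Hochberg adjustment depends on the share of genes that change. In the real data 29.6% of genes had an unadjusted p under 0.05, so these percentages do not give the test's power there. Camera called 1 of 100 unchanged simulated lists at p under 0.05, with genes simulated as independent, which does not test the effect of correlated genes. Figures were drawn with matplotlib.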

Results

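The data were 6 RNA-seq libraries of mouse intestinal epithelium, 3 from mice gavaged with Candida albicans and 3 from mice gavaged with PBS, all labelled Apoe-/-. Totals were 24891735, 22670389 and 21406930 counts for PBS replicates 1 to 3 and 23209209, 23422950 and 24883060 for Candida albicans replicates 1 to 3. The single comparison asks how repeated exposure to the yeast alters gene expression in the gut epithelium of mice prone to atherosclerosis. Fold changes below are Candida albicans against PBS.

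Among the genes of lowest p, Ugt1a1 and 3 cytochrome P450 genes were on the higher side and the tuft cell markers Dclk1 and Ptgs1 on the lower side, but no single gene passed the adjusted threshold. Ugt1a1, a glucuronosyltransferase that conjugates bilirubin and drugs (ENSMUSG00000089960, chromosome 1, 88211959 to 88218997, mm10), had 33.6 ± 1.81 CPM with Candida albicans and 8.86 ± 1.36 CPM with PBS (counts scaled to library size, mean ± SD, n = 3 each). Its log2 fold change was 1.92 (SE 0.16). Retsat, which saturates retinol, had a log2 fold change of 1.96, and the cytochrome P450 genes Cyp2j13, Cyp3a25 and Cyp2c65 had 3.24, 2.75 and 1.64. Barx2 (2.22), Ocm (1.46), Pank3 (1.03), Bend7 (0.96) and Pgm3 (0.90) completed the 10 higher genes of lowest p. On the lower side, Selenom, a selenoprotein (ENSMUSG00000075702, chromosome 11, 3514684 to 3517351), had 19.9 ± 0.81 CPM with Candida albicans and 53.0 ± 4.49 CPM with PBS, a log2 fold change of -1.41 (SE 0.11). Pygl (-2.14), Dclk1 (-1.99), Kctd12 (-1.90), Pik3r5 (-1.86), Ptgs1 (-1.76), Bex3 (-1.57), Kit (-1.38), Hmgn1 (-1.11) and Marcks (-0.83) followed. In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 0 of 16313 genes reached an adjusted p under 0.05 and the smallest value was 0.054, with 0 in each direction. At an adjusted p under 0.1 there were 1078 higher and 985 lower genes, and at an unadjusted p under 0.05 there were 4827 (2182 higher, 2645 lower) where chance gives 816. The groups did not overlap for 35.6% of genes, against 10% by chance. The count of 0 depended on the tool, the count filter, the scaling, the replicate block and 1 library: the DESeq2 Wald test called 1414 higher and 1024 lower genes, limma-voom 0 and 0, voom with quality weights 1232 and 1337, and edgeR without PBS replicate 1 gave 1695 and 925. With all 6 libraries edgeR gave 295 and 257 with no count filter, 10 and 32 at a mean of 5 CPM or more, and 14 and 174 under library totals only. With the replicate number as a block, which is not shown to pair the libraries, edgeR gave 1030 and 1050. The median log2 fold change of all genes was -0.16 under TMM, -0.08 under DESeq2 size factors, -0.20 under upper quartile scaling and -0.45 under library totals, and the share of unadjusted calls that were higher was 45.2%, 54.5%, 41% and 13.8% in that order.

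Tuft cell markers were lower with Candida albicans in every tested member. Tuft cells are rare chemosensory epithelial cells, and all 17 tested members of their list were lower in all 3 Candida albicans libraries than in any PBS library, with a median log2 fold change of -1.77. All 17 passed when adjusted over the list alone, and 0 passed over all genes. Dclk1, a widely used tuft cell marker (ENSMUSG00000027797, chromosome 3, 55242364 to 55539068), had 59.1 ± 3.68 CPM with PBS and 14.9 ± 4.60 CPM with Candida albicans. Ptgs1, a prostaglandin synthase, had 26.3 ± 4.30 and 7.75 ± 0.44 CPM. Alox5ap, needed to make leukotrienes, had 13.9 ± 2.29 and 3.13 ± 0.94 CPM. Pou2f3, the transcription factor that specifies tuft cells, had a log2 fold change of -2.28 (SE 0.37), and Trpm5, their taste-type cation channel, -1.74 (SE 0.30). Camera gave an adjusted p of 2.09e-22 with the preset correlation and fry an adjusted p of 0.037, while camera gave an adjusted p = 0.42 with an estimated correlation. Mitochondrially encoded genes and smooth muscle markers were also lower in mean in the Candida albicans libraries.

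**Figure D1:**
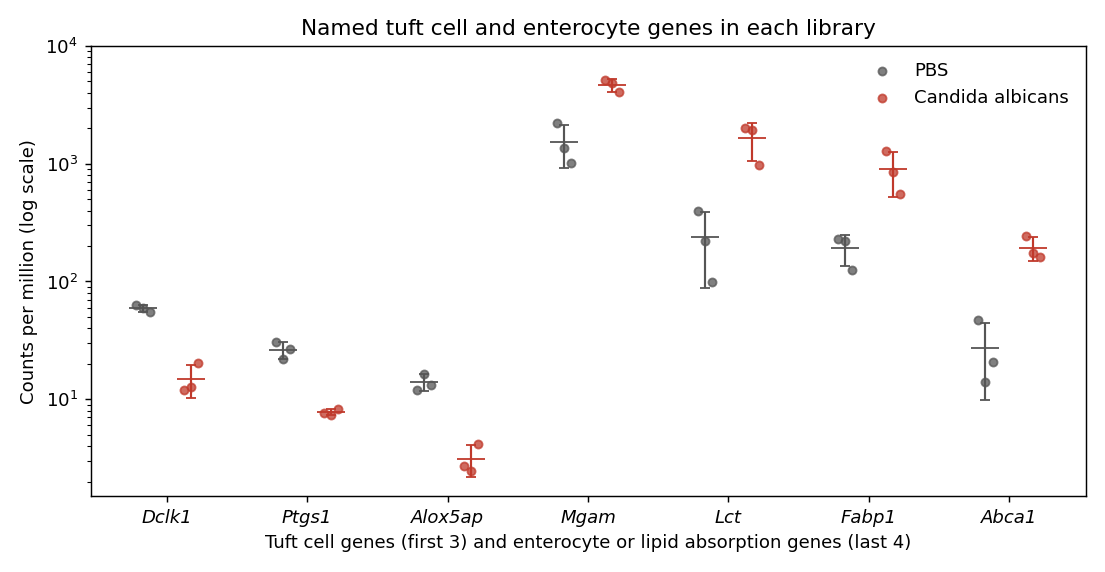
CPM (log scale) of 3 tuft cell genes and 4 enterocyte or lipid absorption genes in each library, grey for PBS and red for Candida albicans, with the mean as a dash and the SD (n = 3) as a bar. The 3 libraries of each group lay apart for each of the 7 genes, with Dclk1 at a mean of 59.1 CPM in PBS and 14.9 CPM with Candida albicans.

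Brush border and fat absorption genes of mature enterocytes were higher with Candida albicans. In the mature enterocyte list 24 of 24 genes had a positive log2 fold change (median 1.31), and 22 passed when adjusted over the list alone. Lct, which encodes lactase (ENSMUSG00000026354, chromosome 1, 128284756 to 128328318), had 239 ± 150 CPM with PBS and 1648 ± 585 CPM with Candida albicans, and Mgam, the maltase-glucoamylase, 1529 ± 619 and 4667 ± 571 CPM. The phosphate transporter gene Slc34a2 had 275 ± 157 and 1136 ± 246 CPM, and the brush border protease gene Mep1b 876 ± 278 and 2090 ± 57.0 CPM. Of the 27 lipid absorption and chylomicron genes, 24 were higher and 1 lower when adjusted over the list alone (median 1.37). Abca1, a cholesterol exporter, had a log2 fold change of 2.83 (SE 0.47), and the fatty acid binding protein gene Fabp1 2.23 (SE 0.38). Abcg8 and Abcg5, whose products form the sterol transporter that returns cholesterol to the lumen, had 1.41 (SE 0.28) and 1.24 (SE 0.25). Scarb1 was the lower member, at -1.22 (SE 0.32). Over all genes 0 members of either list passed. Camera gave adjusted p values of 1.25e-18 (enterocyte) and 2.11e-19 (lipid absorption) with the preset correlation, and an adjusted p = 0.50 for each with an estimated correlation. Fry gave adjusted p values of 0.099 and 0.092. Without PBS replicate 1 the log2 fold changes of Lct, Abca1 and Slc34a2 were 3.48, 3.60 and 2.71, against 2.79, 2.83 and 2.05 with all libraries. Smooth muscle markers and the mitochondrial share, given below, were lower in mean in the same Candida albicans libraries, and for the mitochondrial share (3.73% against 6.89%) the groups did not overlap.

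Xenobiotic, fatty acid oxidation, ceramide, proximal intestine, junction and clock lists were also higher by camera with the preset correlation. Adjusted over the list alone, 11 of 22 xenobiotic metabolism genes passed, all higher, among them Ugt1a1, Cyp2c65, Cyp3a25 and Cyp2c66 (log2 fold change 2.42, SE 0.32). Camera's adjusted p was 1.58e-11, fry's 0.072, and adjusted p = 0.42 with an estimated correlation. Of 23 fatty acid oxidation and PPAR alpha target genes, 11 passed over the list alone, all higher. Acadvl, of very long chain fatty acid oxidation, had a log2 fold change of 0.80 (SE 0.13), and Acaa1b, Acaa1a and Ehhadh, of peroxisomal oxidation, had 2.08, 0.77 and 0.72. Its adjusted p was 3.08e-08 by camera, 0.044 by fry, and adjusted p = 0.42 with an estimated correlation. Of 13 genes in the ceramide consumption list, 5 passed over the list alone, all higher. They included the glucosylceramide synthase gene Ugcg (1.24, SE 0.33) and Sgms2 (0.64), whose products use ceramide. The sphingosine-1-phosphate lyase gene Sgpl1 (1.72, SE 0.42) and Sphk2 (0.54) were also among them. Their products act on sphingosine-1-phosphate and sphingosine, not on ceramide itself. Without PBS replicate 1 Sgpl1 had 2.38. This list's adjusted p was 0.000165 by camera, 0.092 by fry, and adjusted p = 0.46 with an estimated correlation. Proximal small intestine markers had 3 of 10 members past the threshold over the list alone (Fabp1, Lct and the incretin gene Gip at 0.95), with Gata4 at 1.08. Of these, Fabp1 is also in the lipid absorption list and Lct in the mature enterocyte list. In all, 7 members had a positive log2 fold change and 3 a negative one, Cybrd1 (-0.70, SE 0.85) and Slc40a1 (-0.26, SE 0.70) among the negative. The proximal list's adjusted p was 0.000781 by camera, 0.037 by fry, and adjusted p = 0.42 with an estimated correlation. Junction genes had 5 of 18 past it, with Cldn15 at 0.93, Ocln at 0.72, Cldn7 at 0.66 and Marveld2 at 0.35 (camera adjusted p 0.000987, fry 0.14, and adjusted p = 0.68 with an estimated correlation). Clock genes had 0 of 17 past it, with Cry2 at 0.82, Per2 at 0.81, Nr1d2 at 0.62 and Clock at 0.36 (camera adjusted p 0.0142, fry 0.27, and adjusted p = 0.68 with an estimated correlation). Without PBS replicate 3 the clock list's camera adjusted p was 0.073, and with the smooth muscle score as a covariate, an alternative chosen after seeing the data, the junction list was not called. The smooth muscle score and the mitochondrial share, given below, were lower in mean in the same Candida albicans libraries.

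Proliferation, stem cell, cholesterol synthesis and interferon lists were lower by camera with the preset correlation. Of 38 cell cycle genes, 37 had a negative log2 fold change (median -0.95) and 24 passed over the list alone, all lower. Mki67, the proliferation marker, had 117 ± 38.5 CPM with PBS and 49.9 ± 7.17 CPM with Candida albicans. Ccne1, Cenpe and Aurka had log2 fold changes of -1.38, -1.37 and -1.14. The list's adjusted p was 6.35e-08 by camera, 0.21 by fry, and adjusted p = 0.79 with an estimated correlation. Stem cell markers had 19 of 21 negative log2 fold changes and 0 past the threshold over the list alone, with Cd44 at -1.47, Smoc2 at -1.23 and Lrig1 at -0.95 (camera adjusted p 0.00442, fry 0.092, and adjusted p = 0.63 with an estimated correlation). Ly6a, a marker of regenerating epithelium that interferon also raises, had a log2 fold change of -5.34 (SE 1.38), and PBS replicate 2 held 1193 CPM against 27.8 and 147 in PBS replicates 1 and 3, so that without PBS replicate 2 it had -2.84. Of 25 cholesterol biosynthesis genes, 12 were lower and 2 higher over the list alone. Mvk and Msmo1 had -1.23 and -0.96, and Sc5d and Stard4 had 0.68 and 0.49. The adjusted p was 0.000754 by camera, 0.26 by fry, and adjusted p = 0.79 with an estimated correlation. Without Candida albicans replicate 1 camera's was 0.063. Interferon response genes had 40 of 41 negative log2 fold changes (median -0.94) and 0 past the threshold over the list alone. Ifit2, Mx1, Mx2 and Stat2 had -3.77, -2.61, -2.35 and -0.96, and in PBS replicate 2 Ifit2 reached 244 CPM and Mx1 193 CPM, against 31.9 and 59.7 CPM and 40.4 and 60.9 CPM in PBS replicates 1 and 3. Without PBS replicate 2 Ifit2 had -2.40 and Mx1 -1.58. The adjusted p was 1.55e-07 by camera, 0.27 by fry, and adjusted p = 0.79 with an estimated correlation. In the same Candida albicans libraries the mean smooth muscle score was 3.05 against 7.24 in PBS, and the mitochondrial share 3.73% against 6.89%.

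HIF genes and the genes of antifungal and antimicrobial defence were not called as lists moving one way, by camera or by fry. Fry's mixed test, of change in either direction, gave adjusted p values of 0.0059 for hypoxia and glycolysis targets and 0.029 for iron absorption. It gave 0.0046 for fungal recognition and type 17 immunity, 0.028 for inducible epithelial defence and 0.073 for HIF pathway components. That test called 22 of the 40 lists. Hif1a and Epas1, which encode HIF-1 alpha and HIF-2 alpha, had log2 fold changes of -0.06 (SE 0.24) and -0.02 (SE 0.21), and both signs turned under DESeq2 size factors (0.01 and 0.05). Camera gave adjusted p values of 0.39 for HIF pathway components, 0.94 for hypoxia and glycolysis targets and 0.39 for intestinal HIF-2 alpha and iron absorption genes. Of the 36 hypoxia and glycolysis targets, 1 was higher and 6 were lower at an unadjusted p under 0.05 in edgeR's test. Adjusted over the list alone, 1 passed, on the lower side. The higher one was Vegfa, the angiogenic growth factor, which had 82.3 ± 42.0 CPM with PBS and 192 ± 12.9 CPM with Candida albicans (log2 fold change 1.22, SE 0.34, adjusted p 0.094, and 1.84 without PBS replicate 1). Slc11a2, the iron importer, had 0.84 (SE 0.22, adjusted p 0.089). Cybrd1 (-0.70), Slc40a1 (-0.26) and Neu3 (-1.07) had standard errors of 0.85, 0.70 and 0.63. Cybrd1 had -1.53 without Candida albicans replicate 1, and Slc40a1 0.53 without PBS replicate 3, 0.07 without Candida albicans replicate 1 and -1.05 without Candida albicans replicate 3. Ceramide production genes gave a camera adjusted p of 0.26, with Smpd3 at 0.54 (SE 0.12), Cers6 at 0.31 (SE 0.16) and Sptlc2 at 0.28 (SE 0.21). Neu3, given above, is also in this list and was lower. The list was divided, with 3 members higher and 4 lower at an unadjusted p under 0.05 in edgeR's test. Its adjusted p in fry's mixed test was 0.0054. The antimicrobial lectin genes Reg3b and Reg3g had 0.80 (SE 0.39) and 0.60 (SE 0.47, and 1.27 without PBS replicate 3), and Clec7a, which encodes the beta-glucan receptor Dectin-1, had -0.72 (SE 0.44). Camera gave 0.55 for inducible epithelial defence, 0.55 for fungal recognition and type 17 immunity and 0.55 for B cell and plasma cell markers. Apoe had -0.42 (SE 0.24) and was counted in both groups, at 83.2 ± 23.3 CPM in PBS and 62.2 ± 12.5 CPM with Candida albicans. This gene-level count goes against a complete loss of the transcript in mice labelled Apoe-/-, and which part of the gene was altered was not examined here. None of these single genes passed the adjusted threshold over all genes in edgeR's test.

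**Figure D2:**
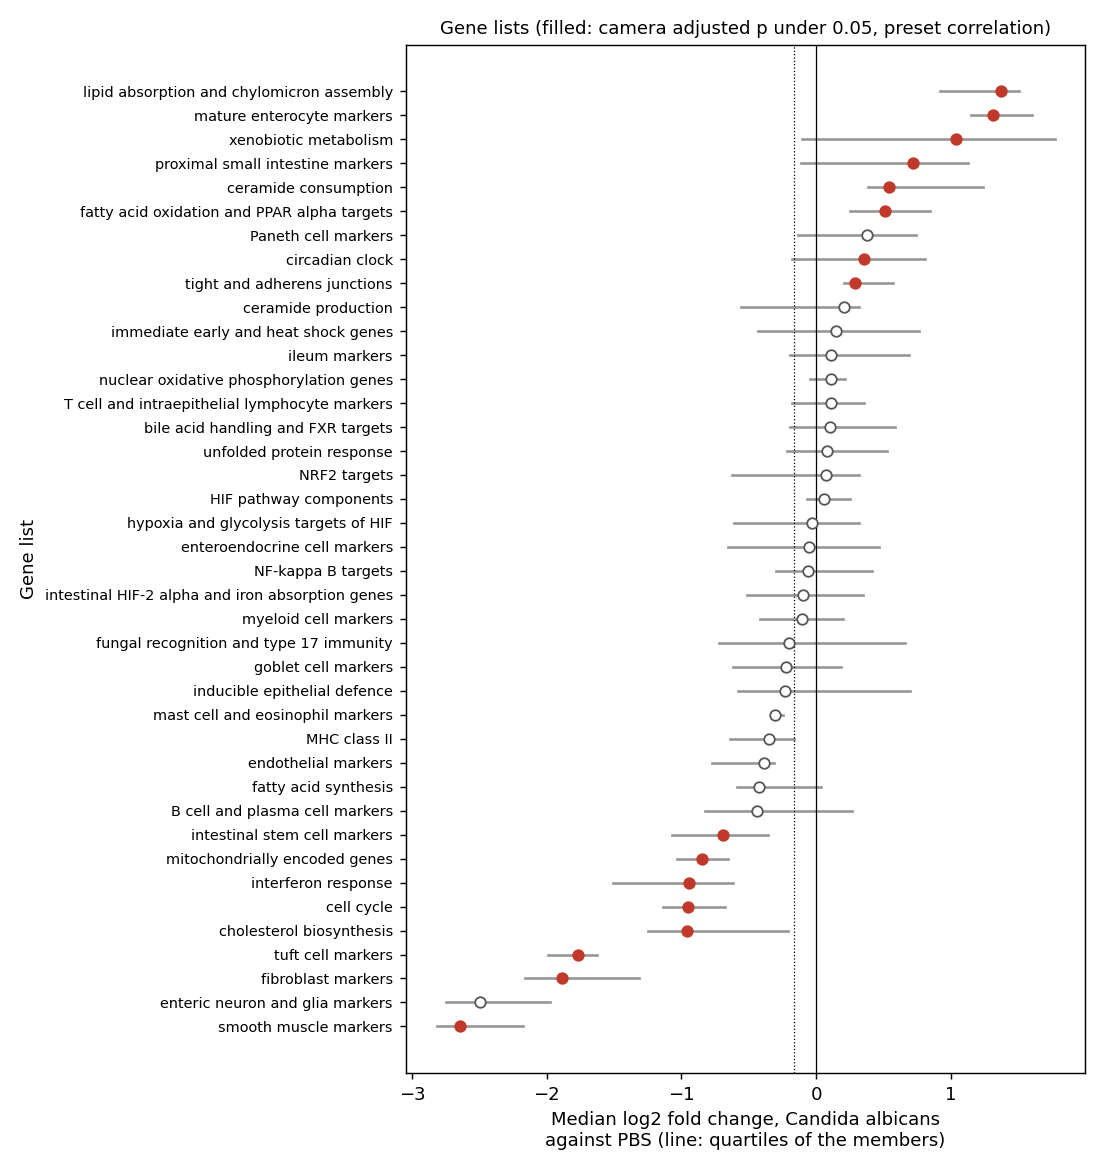
Median log2 fold change of Candida albicans against PBS for the 40 gene lists tested, with a line for the quartiles of the members; filled points had a camera adjusted p under 0.05 with the preset correlation, and the dotted line marks the median of all genes, -0.16. Tuft cell markers sat at -1.77 and lipid absorption genes at 1.37, and with an estimated correlation 0 lists were called.

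Markers of the gut wall varied widely between libraries within both groups. The smooth muscle score, a mean log2 CPM, was 8.85, 5.06 and 7.80 in PBS replicates 1 to 3 and 6.86, 1.96 and 0.32 in Candida albicans replicates 1 to 3, and the groups overlapped (exact permutation p = 0.2, two-sided). Smtn, Tagln, Synpo2 and Mylk had log2 fold changes of -2.07, -1.77, -2.85 and -1.10 with standard errors of 0.87, 0.92, 1.63 and 0.64. Smooth muscle markers gave a camera adjusted p of 0.00856 and fibroblast markers 0.00486, with an adjusted p = 0.79 for each with an estimated correlation and 0 members past the threshold over the list alone. Among fibroblast genes Fn1, Col6a1, Col3a1 and Col1a1 had -3.47, -2.18, -2.17 and -2.08. Without PBS replicate 1 both lists had a camera adjusted p of 0.10, and Smtn, Tagln, Synpo2 and Mylk had -1.25, -0.66, -1.87 and -0.31 and Fn1, Col6a1, Col3a1 and Col1a1 -2.72, -1.36, -1.30 and -1.16. Without Candida albicans replicate 1 Smtn, Tagln and Synpo2 had -3.23, -2.54 and -6.52 and the 4 fibroblast genes -4.99, -3.00, -3.37 and -3.70. The first principal component held 58.5% of the variance and followed the smooth muscle score (Pearson's r = -0.981, exact permutation p = 0.0014, adjusted p 0.0028; Spearman's rho = -1, exact permutation p = 0.0028, adjusted p 0.0056; n = 6, 1 of 2 relations computed). Pearson's r was -0.906 without the 2 libraries farthest from the median score. The component was computed over all tested genes, the 10 smooth muscle markers among them, so it is partly built from the score it is compared with. Within PBS r was -0.992 and within Candida albicans -0.989, over 3 libraries each and without a test. PBS replicate 1 and Candida albicans replicate 1 had the highest rank correlation with each other of any pair across the groups (rho = 0.97). The mitochondrial share and the first component gave r = -0.674 (exact permutation p = 0.15, adjusted p 0.15) and rho = -0.543 (exact permutation p = 0.30, adjusted p 0.30; n = 6). Without the 2 libraries farthest from the median share r was -0.959, and it was -0.622 within PBS and 0.919 within Candida albicans, so its sign differed between the groups, which was not tested.

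**Figure D3:**
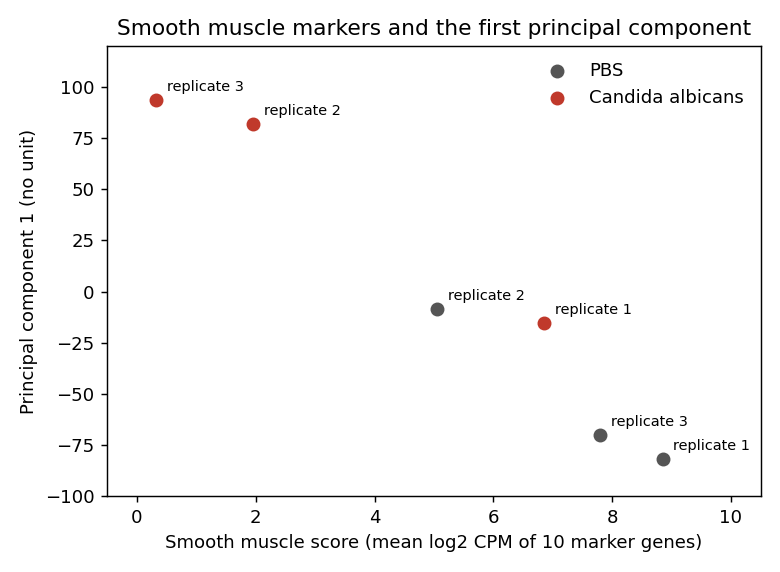
First principal component of log2 CPM (no unit) against the smooth muscle score (mean log2 CPM of 10 markers) for each library, grey for PBS and red for Candida albicans. Scores ran from 0.32 to 8.85 and the component fell along them in both groups, with r = -0.981 over the 6 libraries.

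Mitochondrially encoded genes took a smaller share of counts with Candida albicans. The 13 protein genes held 6.89 ± 1.49% of counts in PBS and 3.73 ± 0.69% with Candida albicans (n = 3 each), a difference of -3.17 percentage points (exact permutation p = 0.1, two-sided, the smallest possible), and the groups did not overlap. mt-Nd2, mt-Nd1, mt-Co3 and mt-Nd3 had log2 fold changes of -0.85, -0.76, -1.07 and -1.04. Camera gave this list an adjusted p of 0.000754, and adjusted p = 0.79 with an estimated correlation, with 0 of 13 members past the threshold over the list alone. Without Candida albicans replicate 1 the camera adjusted p was 0.064. Nuclear oxidative phosphorylation genes had a median log2 fold change of 0.11 and a camera adjusted p of 0.11, or 0.0398 (higher) under DESeq2 size factors, and adjusted p = 0.82 with an estimated correlation.

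The other lists were not called in the main test, though the scaling or 1 library decided several of them. Camera adjusted p values were 0.94 for goblet cells, 0.55 for Paneth cells, 0.49 for enteroendocrine cells, 0.16 for ileum markers, 0.38 for bile acid handling, 0.27 for fatty acid synthesis, 0.058 for the unfolded protein response, 0.55 for NRF2 targets, 0.16 for immediate early and heat shock genes and 0.20 for NF-kappa B targets. They were 0.39 for MHC class II, 0.39 for T cells and intraepithelial lymphocytes, 0.94 for myeloid cells, 0.34 for mast cells and eosinophils, 0.39 for endothelium and 0.066 for enteric neurons and glia. These p values and the calls that follow used the preset correlation. With an estimated correlation and all 6 libraries the adjusted p was 0.92 for Paneth cells, 0.87 for MHC class II and for B and plasma cells, 0.82 for ileum markers, enteric neurons and glia, immediate early genes and nuclear oxidative phosphorylation genes, and 0.79 for the unfolded protein response. Under DESeq2 size factors camera called the unfolded protein response higher (0.0464) and enteric neurons and glia lower (0.0312). Without Candida albicans replicate 1, camera called Paneth cells (1.04e-07), ileum markers (0.037) and the unfolded protein response (0.012) higher, and MHC class II (1.63e-06), B and plasma cells (0.00013) and enteric neurons and glia (0.000636) lower. Without PBS replicate 2 it called ileum markers (0.00856), the unfolded protein response (0.0034) and nuclear oxidative phosphorylation genes (0.0155) higher and enteric neurons and glia (0.000375) lower. Ileum markers were also called higher without Candida albicans replicate 2 (0.0309), the unfolded protein response without PBS replicate 3 (0.0437), and immediate early genes (0.0151) and nuclear oxidative phosphorylation genes (0.0174) without Candida albicans replicate 3. Colon, erythroid and pancreatic acinar markers had 4, 4 and 2 tested members, too few for camera, with median log2 fold changes of -0.29, -0.04 and 0.49. Camera's direction was up for 7 lists with a negative median: goblet cells, enteroendocrine cells, B and plasma cells, inducible defence, type 17 immunity, NF-kappa B targets and the iron absorption list. NRF2 targets had a median of 0.07 and a mean of -0.07. Under library totals only, where the median of all genes was -0.45, 9 lists with a positive median under TMM had a negative one: HIF pathway (-0.22), unfolded protein response (-0.21), NRF2 targets (-0.19), T cells (-0.19), nuclear oxidative phosphorylation (-0.18), bile acid handling (-0.16), ileum (-0.15), immediate early genes (-0.13) and ceramide production (-0.08). Under that scaling the medians of the called junction and clock lists were 0.02 and 0.07, against 0.29 and 0.36 under TMM. Under DESeq2 size factors the medians of hypoxia and glycolysis targets (0.05), NF-kappa B targets (0.02), enteroendocrine cells (0.03) and erythroid markers (0.05) turned positive.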

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

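The smooth muscle covariate, legacy=FALSE and the removal of replicate 1 of both groups were chosen after seeing the data. Counts of genes with an adjusted p under 0.05, 0 higher and 0 lower in the main test, were 0 and 0 with DESeq2 size factors, limma-voom, robust=FALSE, legacy=FALSE and without mitochondrially encoded genes. They were 1 higher and 2 lower with upper quartile scaling, 14 and 174 with library totals only, 1414 and 1024 with the DESeq2 Wald test, 1232 and 1337 with voom quality weights, 295 and 257 with no count filter, 10 and 32 at a mean of 5 CPM or more, 14 and 26 with the smooth muscle covariate, and 1136 and 974 without replicate 1 of both groups. Leaving out 1 library gave 0 to 1695 higher and 0 to 925 lower genes, and every call came without PBS replicate 1. Genes at an unadjusted p under 0.05 ranged from 3156 (without Candida albicans replicate 2) to 5621 (without PBS replicate 1) when 1 library was left out, against 4827, and from 3773 to 6238 under the other settings. The smallest adjusted p was 0.054 in the main test, and the cause of these differences was not tested. With the replicate number as a block, 1030 genes were higher and 1050 lower, and 8 lists higher and 9 lower, enteric neurons and glia (0.00878) among them. The numbers are not shown to pair the libraries: deviations of same-numbered libraries correlated at 0.576, 0.357 and 0.046, and PBS replicate 2 correlated best with Candida albicans replicate 3 (0.408).

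Camera called 8 lists higher and 8 lower. With an estimated correlation it called 0 and 0, and adjusted p values were 0.422 for tuft cells, 0.504 for mature enterocytes, 0.504 for lipid absorption and 0.793 for the cell cycle. Fry called 2 higher and 1 lower, with 0.0988 for mature enterocytes, 0.0919 for lipid absorption and 0.21 for the cell cycle. Fry's mixed test, of change in either direction, called 22 lists. Under the other settings 8 to 11 lists were higher and 6 to 9 lower. Those 4 lists stayed called when any 1 library was left out, with highest adjusted p values of 1.48e-13 (tuft), 4.31e-13 (enterocyte), 3.33e-14 (lipid) and 0.000509 (cell cycle). Calls that ended were cholesterol biosynthesis (0.0626) and mitochondrially encoded genes (0.0642) without Candida albicans replicate 1, the clock list without PBS replicate 3 (0.0734), and fibroblast and smooth muscle markers without PBS replicate 1 (0.103 each). The mitochondrial list was also lost without replicate 1 of both groups, and the junction list with the smooth muscle covariate. With that covariate fibroblast and smooth muscle markers turned up at adjusted p values of 0.971 and 0.943, the smooth muscle list being what the covariate is built from. By the preset correlation, lists not called in the main test were called with that covariate, goblet (0.0127) and Paneth cells (0.000447) reversed to lower and T cells higher (0.000411). By camera with an estimated correlation and no covariate, their adjusted p values were 0.98, 0.92 and 0.87. Without replicate 1 of both groups Paneth cells were called higher (0.000392) and MHC class II lower (0.000354). B and plasma cells reversed to lower without replicate 1 of both groups (0.000486) and without Candida albicans replicate 1 (0.00013), with adjusted p values up to 0.758 when another library was left out. The mitochondrial share differed by -3.17 points, by -3.17 without the 10 most abundant nuclear genes, and by -3.80 to -2.34 with 1 library left out.

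Of 1810 log2 fold changes of the 91 named genes under alternatives, 1787 kept their sign, 401 passed the threshold and 23 reversed, in 9 genes. With the smooth muscle covariate Col3a1 (0.20), Col1a1 (0.21), Tagln (0.27), Mylk (0.29), Cybrd1 (0.47) and Sptlc2 (-0.058) reversed. Epas1 reversed with DESeq2 size factors (0.052), the DESeq2 Wald test (0.062), limma-voom (0.008), the replicate block (0.001), without replicate 1 of both groups (0.25), and without PBS replicate 1 (0.18), PBS replicate 2 (0.16), Candida albicans replicate 1 (0.05) or Candida albicans replicate 2 (0.02), and ranged from -0.174 to 0.18 with 1 library left out. Hif1a reversed with DESeq2 size factors (0.011), the DESeq2 Wald test (0.019), without replicate 1 of both groups (0.084), and without PBS replicate 1 (0.12), PBS replicate 2 (0.15) or Candida albicans replicate 3 (0.08), in a range of -0.23 to 0.15. Slc40a1 reversed without PBS replicate 3 (0.53) or Candida albicans replicate 1 (0.07), in a range of -1.054 to 0.53. Apart from the covariate, the cause was not tested. Depth limits the least abundant of these genes: Cybrd1 had 0.0848 CPM in Candida albicans replicate 3, under the 0.127 CPM that a count of 0 allows there.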

Other observations

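The tests of crypt content, of goblet against enterocyte genes and of tuft against other secretory genes were chosen after the results were seen, as were the smooth muscle covariate in the gene test, the removal of replicate 1 of both groups, the look at the reshuffled scores and the genes singled out here. Retnlb, a goblet cell protein that type 2 cytokines raise, had 6.65, 54.1 and 16.6 CPM in PBS replicates 1 to 3 and 0.247, 0.523 and 0.382 CPM in Candida albicans replicates 1 to 3 (log2 fold change -6.05, SE 0.93, edgeR adjusted p 0.073). Reg3a, an antimicrobial lectin gene, had a log2 fold change of 1.499 (SE 0.33). The IgA heavy chain gene Igha and the joining chain gene Jchain had 48.7 ± 24.5 and 14.7 ± 7.74 CPM in PBS and 197 ± 70.3 and 54.3 ± 10.9 CPM with Candida albicans (adjusted p 0.081 and 0.084). Of the 59 immunoglobulin segments tested, 8 were higher and 0 lower at an unadjusted p under 0.05, and 0 passed the adjusted threshold. Fatty acid synthesis genes divided: Fasn, Acly, Acaca, Acacb and Fads1 were lower when adjusted over the list alone (log2 fold changes -1.10, -0.54, -0.54, -1.15 and -1.32), while Srebf1 was higher (0.85). The non-coding gene Gm26917 had 0.171 ± 0.073% of counts in PBS and 0.0128 ± 0.0006% with Candida albicans (exact permutation p = 0.1, the smallest possible). The shares of mitochondrial rRNA genes (0.285% in PBS, 0.178% with Candida albicans) and of pseudogenes (0.732% and 0.574%) were lower too. Each had an exact permutation p of 0.1, and the cause of these differences in share was not tested. Over all genes, none of the single genes given here passed the adjusted threshold in edgeR's test.

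Tuft cell markers were lower with Candida albicans in every library. Dilution by the larger enterocyte RNA would lower other secretory cells alike, but the change of the tuft score differed from the mean change of the goblet and enteroendocrine scores by -1.614 log2 units (95% interval -2.173 to -1.055), which argues against it. Less tuft cell RNA as a whole predicted that tuft genes outside the list would be lower too: 15 of 16 were, with a median log2 change of -1.538 (-1.825 to -1.439, bootstrap over genes, which are not independent). A stronger type 2 response in the PBS mice may also contribute, since a score of 9 epithelial genes that type 2 cytokines raise was lower by -0.672 (95% interval -1.291 to -0.053). That score rested on Gsdmc2, Gsdmc3, Gsdmc4 and Pla2g4c (log2 fold changes -1.32, -1.23, -1.17 and -2.11), with Ang4 at -0.86. Clca1 (-0.18) and Il4ra (-0.18) changed little, and Fcgbp (0.89) and Itln1 (0.38) went the other way. The score's exact permutation p was 0.1, the smallest possible, and cell numbers were not measured.

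Enterocyte and lipid absorption genes were higher, with a joint score difference of 1.416 log2 units. Removing a trend on GC content and gene length left a median log2 change of 1.592 for these genes, against 1.31 before. The median did not shrink, which argues against such a bias as the source. Its interval (1.444 to 1.687) came from a bootstrap over genes, which are not independent, and does not measure the spread between libraries. Smooth muscle carry-over in PBS cannot be told apart from a treatment effect: with the smooth muscle score as a covariate, a test set before its result was seen, the difference was 1.673 with an interval that includes 0 (-0.359 to 3.705). The difference did not shrink, and Candida albicans replicate 1 had a higher smooth muscle score than PBS replicate 2 and a higher enterocyte score (10.69 against 9.10), but a single pair of libraries excludes nothing. A further test, chosen after that one had left the question open, did not settle it either, as the difference from the goblet score was 1.513 (-0.282 to 3.308). Fewer crypts in the collected tissue also cannot be told apart with 6 libraries, as the Paneth score minus the cell cycle score differed by 0.783 (-1.256 to 2.823).

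The 0 calls went with a wide spread between libraries. Uneven smooth muscle carry-over is a candidate explanation that cannot be told apart here: a model with the smooth muscle score called 40 genes, while 60 reshuffled scores called a median of 0, and 9 of the 61 called as many as the real one, up to 2808. That share was to argue against it. However, 7 of the 8 reshuffled scores with as many calls followed the real score within the groups, up to sign (absolute r of 0.686 to 0.987, against a median of 0.37 over all 60). Other reshuffled scores that followed it called 0 genes, at absolute r of up to 0.849, so following it did not by itself bring calls. Of the 35 with an absolute r under 0.5, 1 called as many. The rule set beforehand thus went against the explanation. It is left open only because scores that follow the real one are no clean comparison, which was judged after the result was seen. Removing PBS replicate 1, the library of highest score, gave 1695 higher and 925 lower genes and removing replicate 1 of both groups 1136 and 974. Removing PBS replicate 3 or Candida albicans replicate 1, the next highest, gave 0. These counts do not decide, since PBS replicate 1 was also the PBS library nearest to Candida albicans in enterocyte and cell cycle scores. Its enterocyte score was 9.74, against 9.10 and 8.13 in PBS replicates 2 and 3. Its cell cycle score was 3.67, against 4.62 and 4.46. Leaving it out widens these group differences whatever its smooth muscle content. The 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05. At an unadjusted p under 0.05 the real split gave 4827 genes and the highest other 1418, so 1 split of the 10, the real one, gave as many; the highest other set PBS replicates 1 and 3 and Candida albicans replicate 1, the libraries of highest smooth muscle score, against the rest. At an adjusted p under 0.05 the real split gave 0 and the highest other 0, and with a real count of 0 all 10 must give as many, so this comparison says nothing. With camera's preset correlation the real split called 16 lists and the highest other 22, and 8 of the 10, the real one included, gave as many, so that most ways of dividing these libraries called as many lists as the treatment did.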
